A study of Mus musculus with 2 samples.

How the data were processed

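DNase-seq maps accessible chromatin by lightly cutting nuclei with DNase I and sequencing the DNA ends, so that the density of cuts is high where DNA is not wrapped in nucleosomes. It was applied to the left cerebral cortex of 2 female mice aged 2 months. Both were B6CASTF1/J animals, the first-generation hybrid of C57BL/6J and CAST/EiJ. Per the labels, the libraries are biological replicates 1 and 2 and come from separately numbered females, although both carry the same donor entry, and they were taken as separate animals on the strength of the replicate and female numbers. All libraries belong to 1 group, so no groups could be compared.

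The authors aligned the reads to mm10, per the labels, and deposited 4 tables of calls for each library. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. Peaks were called by the authors on each library alone, as a larger list at a false discovery rate (FDR) of 0.05 and a smaller list at 0.001. The threshold of each list was read from the values: every peak of a list holds a position below that FDR in the same library's cut-rate table. The signal of a peak is the authors' deposited height of the cut density, normalized by them to read depth. The signal values were whole multiples of a fixed step in each library, within a tolerance of 0.05 of a step, among values below 1000 steps. Read as 1 cut after scaling to 1 M cuts, the step corresponds to 206 M cuts in replicate 1 and 208 M in replicate 2, so the depths differed little. Footprints are short protected stretches inside accessible DNA; the deposited footprint tables give the FDR of the call as a fraction, which is 0.01 throughout. The cut-rate tables hold deposited q-values, that is, the FDR (an adjusted p-value) of the local cut rate for stretches of base pairs, and list values below 0.05. Filtering of alignments before these steps was done by the authors and could not be examined from the calls. The signal is comparable between libraries only as far as scaling to read depth makes it so, and peak numbers also depend on depth and on the share of cuts that fall in accessible DNA. Reads from the CAST/EiJ copy of the genome that differ from the reference may align less often, which would lower signal at such places; alleles were not analysed here.

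Coordinates are 1-based on mm10, and sequence and genes came from GRCm38.p6, the same build, with GENCODE M21. The larger peak list was the main one. Peaks of both libraries that overlapped by at least 1 bp were merged, and a merged peak with members in both libraries was called shared. The percent of shared peaks was set beside 100 random placements of the peaks on their chromosomes. Hotspots are listed cut-rate stretches, joined where they touch, of at least 50 bp. A merged peak was assigned to a promoter when its centre lay within 1 kb of any annotated transcription start site (TSS), and otherwise to exon, intron or intergenic sequence in that order. A peak was called distal when its centre lay more than 1 kb from every TSS. A gene had a promoter peak when a peak reached within 500 bp of its annotated outermost 5′ end, so genes that start mainly at an internal TSS can lack a promoter peak.

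The 26 gene lists, the 26 consensus motifs, the tests and most of the alternatives were fixed before the data were examined. The lists hold markers of cell types of the cortex, markers of other brain regions and of other tissues as controls, and genes of neuronal function, imprinted genes and ribosomal proteins. Of 487 list entries, 481 were found as protein-coding genes, 5 were not protein-coding and 1 was not found. Some lists share members: the excitatory neuron and telencephalic transcription factor lists both hold Neurod2, Neurod6 and Tbr1, and the lymphocyte list shares Bcl11b with the deep-layer and telencephalic lists. Promoter peaks were compared between each list and all other protein-coding genes with a two-sided Fisher's exact test. For distal peaks, each gene's number of shared distal peaks within its body and 10 kb on either side was turned into its percentile among the 200 protein-coding genes of closest locus length. The median percentile of a list was tested two-sided against 10000 random lists of the same size matched on locus length in 20 bins; the smallest p this permutation test can give is 0.0002. Motif matches on either strand were counted in 150 bp windows centred on distal shared peaks and in as many control windows on the same chromosome, outside every hotspot and within 2 percentage points of the same GC content. Footprints overlapped by a match were compared with intervals of the same width moved within the same peaks to places outside footprints. Both used a two-sided Fisher's exact test. P-values were adjusted by the Benjamini-Hochberg method over the 26 lists or the 26 motifs, with a threshold of 0.05. These tests run across genes, peaks or footprints, which are not independent animals, and describe these 2 libraries. The difference between the animals is the median log2 ratio of signal, replicate 1 over replicate 2, at shared distal peaks in a list's loci after subtracting the median of all such peaks, with its percentile among 10000 random lists; with 1 library per animal it has no p-value.

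The genes named in the text follow a rule set in advance: for each list the 3 members with the highest and the 1 with the lowest distal percentile, and a fixed set of marker genes. The rule gave 121 genes, some of which are not reported here. The rule also names the 5 shared peaks with the highest mean rank of signal and, for each library, the 5 strongest peaks that touch no hotspot of the other. Genes named outside it are said to have been chosen after their values were seen. Values are given as mean ± SD with n = 2, 1 library per animal.

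Alternatives covered the upper 50% of the peaks by signal, reciprocal overlap of 50%, hotspots in place of peaks, promoter windows of 1 kb and 2.5 kb, loci of 50 kb, a background matched on promoter CpG number in 10 bins, other control windows, a motif window of 100 bp, other footprint sets, and each library alone. The smaller peak list and control windows matched on both GC and CpG number were added after seeing the data. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. The steps were tested on simulated data. Lists of 20 genes had their distal counts multiplied by 2 or by 4, with random extra peaks added. They were called in 100% of cases over 21727 genes, and unchanged lists in 0%. Because of the extra peaks, and because lists of each size of rise were adjusted apart, this does not give the power for a plain 2-fold rise. The promoter test called 95% of lists planted at 95% and 0% of unchanged lists, and the motif search found 100% of planted copies.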

Results

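Accessible chromatin was mapped by DNase-seq in the left cerebral cortex of 2 female B6CASTF1/J mice aged 2 months, 1 library per animal, called replicate 1 and replicate 2. The labels state no question beyond the tissue and name a single group, so the data were read for where the accessible sites of adult cortex lie, which genes and sequence motifs they belong to, and how closely the animals resembled each other. Signal values corresponded to 206 M cuts in replicate 1 and 208 M in replicate 2. Replicate 1 had 128323 peaks and replicate 2 had 119651, a mean of 123987 ± 6132 (SD, n = 2), which covered 27.3 ± 3.21 Mb (SD, n = 2) with a median width of 200 bp. Footprints numbered 340109 and 284674 with a median width of 9 bp, and 76.4% and 78.3% of the peaks held at least 1.

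The accessible sites with strong signal were found in both animals, whereas weak sites often appeared in 1 animal. Of the peaks, 66.7% in replicate 1 and 72.6% in replicate 2 overlapped a peak of the other animal, against 2.20% for randomly placed peaks. Among the tenth of peaks with the highest signal the share was 99.3% and 99.8%, and among the tenth with the lowest it was 12.9% and 20.5%. Merging gave 154220 peaks, of which 80522 were shared, 41367 were in replicate 1 only and 32331 in replicate 2 only. Across 80487 shared peaks on chromosomes 1 to 19 and X, log2 signal in the animals had Spearman's rho of 0.941 and Pearson's r of 0.956, and 99.2% of the peaks lay within 2-fold of each other after centring. These correlations are across peaks, which are not independent replicates, and across all 154149 merged peaks on these chromosomes the FDR of the cut rate gave a Spearman's rho of 0.504. Of the footprints, 39.5% in replicate 1 and 47.0% in replicate 2 overlapped a footprint of the other animal.

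Promoters held more of the shared peaks than their share of the genome, and introns and intergenic sequence held most of the rest. Of the shared peaks, 29.3% were centred within 1 kb of a TSS, against 4.40% of the genome, a ratio of 6.66. Exons held 5.28% of the shared peaks (2.98% of the genome), introns 36.1% (41.4%) and intergenic sequence 29.3% (51.2%). Of the peaks found in 1 animal, 12.4% (replicate 1 only) and 14.9% (replicate 2 only) lay at promoters. The strongest shared peak lay on chromosome 17 from 39846781 to 39846920, within 1 kb of a TSS at CT010467.1, with a signal of 66.4 ± 5.06 (SD, n = 2). The next were in an exon of Lars2, which encodes the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123461881 to 123462120; 37.6 ± 3.63), in intergenic sequence on chromosome 3 (5860361 to 5860530; 33.0 ± 0.30), in an intron of Il31ra, a cytokine receptor gene (chromosome 13, 112578161 to 112578340; 31.9 ± 7.90), and in intergenic sequence whose nearest protein-coding TSS is that of Igf2bp3 (chromosome 6, 49236421 to 49236620; 29.4 ± 7.47). In all 5, between 60.5% and 100% of the 31-base words also occurred elsewhere in the nuclear genome, against a median of 0% over 1000 random shared peaks, so reads of those words had more than 1 possible place.

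Genes of excitatory neurons, immediate early genes and ribosomal protein genes had promoter peaks more often than other genes, and genes of tissues outside the brain had them less often. Of all 21727 protein-coding genes, 12926 (59.5%) had a shared promoter peak, with a median signal of 2.91 where present in both. The excitatory neuron list had such a peak at 17 of 18 genes. Camk2a, a calcium-dependent kinase of excitatory synapses (chromosome 18, 60925618 to 60988152), had a promoter signal of 3.0 ± 0.43 (SD, n = 2). Slc17a7, the vesicular glutamate transporter of most cortical excitatory neurons (chromosome 7, 45163949 to 45176142), had 1.45 ± 0.01 (SD, n = 2), and Neurod2, a neuronal bHLH factor, 2.00 ± 0.14 (SD, n = 2). Of the immediate early genes, which neurons switch on with activity, 19 of 20 had a promoter peak. Among them were Arc, which encodes a synaptic protein (chromosome 15, 74669083 to 74672570; 6.46 ± 0.82), Nr4a3, an orphan nuclear receptor gene (3.45 ± 0.15), Egr3, a zinc finger factor gene (3.34 ± 0.67), and Fos, which encodes an AP-1 subunit (2.95 ± 0.17; SD, n = 2 each). The exception was Homer1, a synaptic scaffold gene, with no promoter peak at its outermost 5′ end. Ribosomal protein genes had 19 of 20, with Rpl3 at 3.66 ± 0.27 and Rpl19 at 3.51 ± 0.45 (SD, n = 2), and Rps14 without.

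Control lists stood at the other end. None of the 20 Hox genes of the hindbrain and spinal cord list, the 20 hepatocyte genes or the 20 muscle genes had a shared promoter peak (0 of 20 each). With a promoter window of 1 kb in place of 500 bp, the muscle list lay −26.7 percentage points from other genes in place of −59.5. Alb, which encodes serum albumin, Hnf4a, a liver transcription factor gene, and Myod1, a master regulator of muscle, had no promoter peak in either library. Epithelial genes had 3 of 20, with none at Krt5, a keratin gene of basal cells; lymphocyte genes 4 of 20; and erythroid genes 3 of 16, with none at Gata1, a regulator of red cell formation. Microglial genes, although from a cell type of the cortex, had 5 of 20. Cx3cr1, the fractalkine receptor gene, and Csf1r, the receptor gene for a growth factor that microglia need, lacked a promoter peak at their outermost 5′ ends in both libraries. Internal start sites were not examined. Mertk, a receptor gene for clearing cell debris, had a promoter peak at 1.05 ± 0.33 (SD, n = 2).

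The other cell types of the cortex passed the test in neither direction with the larger peak list. Astrocyte genes had promoter peaks at 14 of 20, with Gfap, an intermediate filament gene, at 2.02 ± 0.31, Slc1a2, the main glial glutamate transporter gene, at 2.01 ± 0.13, and Sox9 at 1.41 ± 0.21 (SD, n = 2), whereas Aqp4, a water channel gene, had none at its outermost 5′ end. Oligodendrocyte genes had 11 of 20, with Mbp, which encodes a main myelin protein, at 2.09 ± 0.20 and Olig2, a lineage factor gene, at 0.726 ± 0.040 (SD, n = 2), and none at Sox10. Oligodendrocyte precursor genes had 10 of 17. Inhibitory neuron genes had 13 of 20, with Kcnc1, a potassium channel gene, at 1.71 ± 0.03, Adarb2 at 0.993 ± 0.260, Gad2, which encodes a GABA-synthesizing enzyme, at 0.680 ± 0.018, Slc32a1, the vesicular GABA transporter gene, at 0.661 ± 0.057, and Lhx6, a factor of interneurons from the medial ganglionic eminence, at 0.441 ± 0.021 (SD, n = 2). Gad1 had no promoter peak at its outermost 5′ end in either library, and Sst had one in replicate 1 alone. Counts were 11 of 15 for upper cortical layers, 14 of 17 for deep layers, 16 of 20 for the glutamatergic synapse, 15 of 19 for ion channels, 13 of 18 for telencephalic transcription factors, 7 of 20 for endothelial cells and pericytes, 9 of 16 for meningeal fibroblasts and 5 of 16 for choroid plexus and ependyma. For neurons of other regions they were 13 of 16 (striatum), 10 of 14 (hippocampus) and 9 of 18 (cerebellum), and imprinted genes had 15 of 21. Cldn5, a tight junction gene of brain endothelium, had a promoter peak in replicate 2 alone.

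In Fisher's exact test with Benjamini-Hochberg adjustment over 26 lists, the adjusted p was 0.00406 for excitatory neurons and 0.00306 for immediate early genes and for ribosomal proteins. Below the other genes, the exact test gave 1.21e-07 for each of the Hox, hepatocyte and muscle lists, 0.000569 for epithelia, 0.0021 for lymphocytes, 0.00406 for erythroid cells and 0.00602 for microglia. With a background matched on the number of CpGs in the promoter, 4 of these 10 calls remained (Hox, hepatocytes, muscle and epithelia, adjusted permutation p = 0.0013 each); the other 6 had an adjusted p between 0.0609 and 1, against 0.000176 to 0.0267 over their 5 other alternatives, and lay closer to their matched background, with 94.4% found and 74.1% by matching for excitatory neurons, 95% and 88.4% for immediate early genes, 95% for ribosomal proteins (4.33 percentage points above matching), 20% and 39.3% for lymphocytes, 18.8% and 26.4% for erythroid cells, and 25% and 26.6% for microglia. With the same background the glutamatergic synapse list lay above (57.4% by matching, 80% found) and the cerebellar list below (79.2% by matching, 50% found). With the upper 50% of the peaks by signal, the endothelial and pericyte list (−45.2 percentage points from other genes), the meningeal list (−30.2) and the choroid plexus and ependyma list (−30.2) also passed below, and the glutamatergic synapse list above (24.9); the endothelial and choroid plexus lists passed in 3 of 5 alternatives each, the meningeal and glutamatergic lists in 1 of 5.

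**Figure D1:**
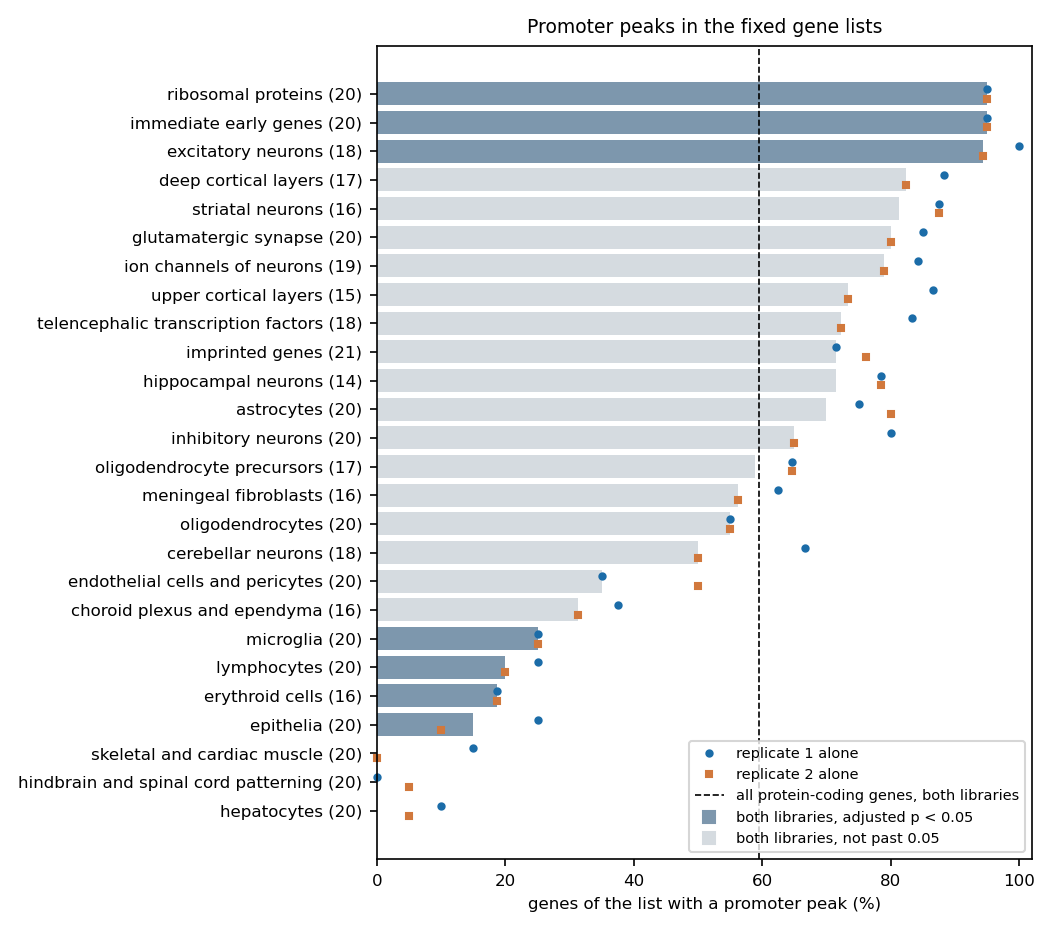
Percent of the genes of each fixed list with a promoter peak; the number of genes is in parentheses. Bars give shared peaks, in the dark shade where Fisher's exact test passed an adjusted p of 0.05; points give each library alone, and can lie below the bar because a merged peak may reach the promoter window through the other library. The dashed line marks all protein-coding genes (59.5%); 3 dark bars lie above it and 7 lists past the threshold below, 3 of them at 0.

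Away from promoters, the loci of telencephalic transcription factors, of excitatory neuron genes and of immediate early genes held more shared peaks than loci of similar length. In the list of telencephalic transcription factors, 17 of 18 genes were at or above the 50th percentile of their length-matched genes, with a median percentile of 93.8 and a median of 6 distal peaks, against 1 over all protein-coding genes. Pou3f2, a POU factor of upper-layer neurons, had 11 distal peaks, Tbr1, a T-box factor of deep-layer neurons (chromosome 2, 61802930 to 61814114), had 9, and Emx1, a homeobox gene of the dorsal telencephalon, had 6. The lowest member was Pax6, with 0. In the excitatory neuron list 16 of 18 genes were at or above the 50th percentile (median 88.3), led by Lingo1 with 24 distal peaks, Slc17a7 with 8 and Tbr1. Camk2a had 10 and Neurod2 had 7, and Nptx1, a neuronal pentraxin gene, had 0. Of the immediate early genes 18 of 20 were at or above it (median 86.6), with 9 distal peaks at Arc, 9 at Nr4a3, 6 at Egr3 and 5 at Fos, but 1 at Bdnf, a neurotrophin gene, and 1 at Homer1.

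More distal peaks than in length-matched genes were also found for hippocampal neurons (median percentile 84.8; 11 of 14 genes at or above the 50th), glutamatergic synapse genes (82.1; 15 of 20), ion channels (77.8; 15 of 19) and imprinted genes (73.3; 17 of 21). Among hippocampal neuron genes, Fibcd1 had 6 distal peaks, and Bok and Plk5 had 4 each. The hippocampal list is a control from another brain region, and it passed in 9 of 9 alternatives. Striatal and cerebellar neurons, also from other regions, did not pass the main test, and neither did upper and deep cortical layers. Passing this test therefore does not by itself set cortex apart from other brain regions. At the synapse, Shank2, a scaffold gene, had 35 distal peaks (percentile 99.5), Gria1, an AMPA receptor subunit gene, 29 and Camk2b 11, while Gria3, an AMPA receptor subunit gene on X, had 0. Among channels, Cacna1c, an L-type calcium channel gene, had 31 and Scn8a, a sodium channel gene, 16, while Scn1a had 2 (percentile 18.3). Among imprinted genes, Impact had 5, Cdkn1c, a cell cycle inhibitor gene, 4 and Ndn 3, and Ube3a, a ubiquitin ligase gene, had 0.

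The remaining 19 lists did not pass the test, and their marker loci ranged from high to low. Mbp had 16 distal peaks (percentile 99.5), Sox9 5 (98.3), Slc1a3, a glial glutamate transporter gene, 8 (96.0), Pecam1, an endothelial adhesion gene, 9 (93.8), Spi1, which encodes PU.1, 4 (91.8), Cux2, an upper-layer homeobox gene, 18 (96.3), and Pou3f3 8 (99.3). Twist1, from the meningeal fibroblast list, had 7 (99.5), and Ppp1r1b, which encodes DARPP-32 of striatal neurons, 8 (98.8). At the low end of these lists were Tek, an endothelial receptor gene, with 0 distal peaks (percentile 4.5), Ugt8a, an enzyme gene of myelin lipids, with 0 (9.75), Tle4 with 1 (11), Mertk with 1 (16), Adora2a, an adenosine receptor gene of striatal neurons, with 0 (18.8), and Gjb6, a connexin gene of astrocytes, with 0 (22.5). Median percentiles were 73.0 for upper and 63.0 for deep cortical layers, 66.4 for inhibitory neurons, 54.4 for astrocytes, 62.9 for oligodendrocytes, 64.8 for oligodendrocyte precursors, 64.5 for microglia, 68.0 for endothelial cells and pericytes, 51.1 for choroid plexus and ependyma and 67.6 for meningeal fibroblasts. They were 61.9 for striatal and 55.8 for cerebellar neurons, 60.9 for the Hox list, 56.3 for erythroid cells, 53.5 for lymphocytes, 60.4 for hepatocytes, 69.4 for muscle, 29.9 for epithelia and 30.3 for ribosomal proteins. The last 2 stood inside their random ranges, with a median of random lists of 43.9 for epithelia and 30.9 for ribosomal proteins, and in replicates 1 and 2 alone they were 56.4 and 28.6 for epithelia and 55.3 and 57.5 for ribosomal proteins.

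The permutation test gave p = 0.0002, the smallest it can give, for telencephalic transcription factors, excitatory neurons and immediate early genes, with an adjusted p of 0.00173 each. Adjusted permutation p-values were 0.0052 for hippocampal neurons, 0.00624 for the glutamatergic synapse, 0.0416 for ion channels and 0.0475 for imprinted genes. Lists below numbered 0, also at an unadjusted permutation p under 0.05. The test could hardly place a list below, because short loci with 0 distal peaks tie with many others. Krt5, with 0 distal peaks, stood at percentile 27.5, beside a lower bound of 28.1 for random lists matched to the epithelial list. That 0 lists lay below therefore does not show that no list had fewer distal peaks. Loci of 50 kb on either side left 3 lists past the threshold (telencephalic, immediate early and hippocampal). The imprinted list was lost in 7 of 9 alternatives (adjusted p 0.026 to 0.765), ion channels in 3 (0.00173 to 0.163), and immediate early genes with a distal limit of 2.5 kb (0.0013 to 0.0511 over 9 alternatives). With the summed signal of the distal peaks in place of their number, the Hox list, a control, also passed above (adjusted permutation p = 0.0319).

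**Figure D2:**
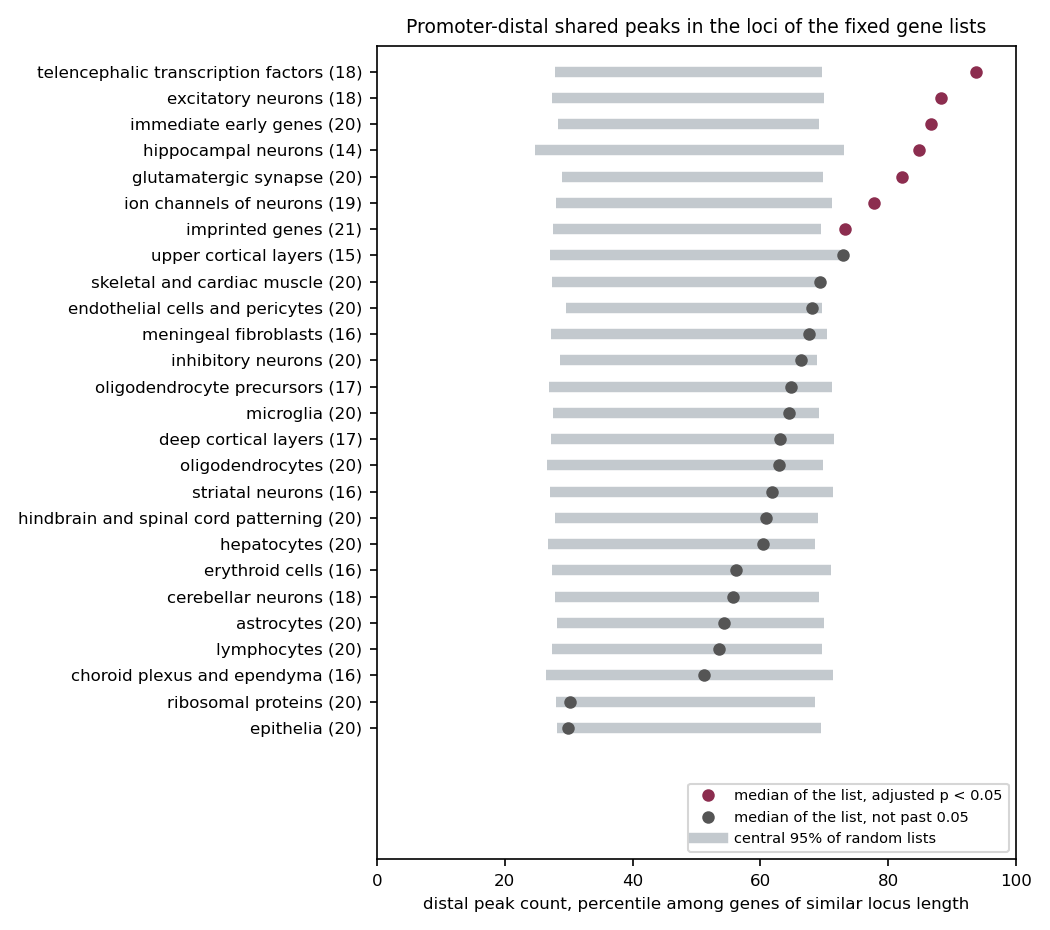
Median percentile of the distal peak count of each fixed list among genes of similar locus length (0 to 100); the number of genes is in parentheses. Points are the lists, coloured where the permutation test passed an adjusted p of 0.05, and grey bars span the central 95% of 10000 random lists of the same size. The 7 coloured points run from 73.3 (imprinted genes) to 93.8 (telencephalic transcription factors).

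Distal shared peaks carried the motif of the architectural protein CTCF far more often than control windows of the same GC content. Motifs of neuronal, activity-dependent and other factors were also enriched. A match does not show which protein was bound. The CTCF motif matched 7.22% of 56658 peak windows and 0.0406% of control windows (log2 ratio 7.44). The AP-1 motif, bound by Fos and Jun proteins, matched 7.15% against 2.22% (1.69), and the NEUROD bHLH motif 3.59% against 0.971% (1.89). Per library, CTCF matched 4.91% ± 0.68, AP-1 6.44% ± 1.12 and NEUROD 3.06% ± 0.42 of all distal peaks (SD, n = 2). Log2 ratios were 3.52 for RFX, 3.27 for EGR, bound by activity-induced zinc finger proteins, 2.76 for NRF1, 2.37 for MEF2, a family active in neurons and muscle, 2.28 for NFI, 2.12 for REST, the repressor of neuronal genes outside neurons, and 1.10 for CRE, the site of CREB. The SP/KLF motif had 1.01, the MYOD bHLH motif 0.93, the POU octamer 0.74, ROR 0.45, TEAD 0.34 and RUNX 0.33. GATA, a motif of blood and endothelial factors, was matched less often than in controls (−0.49; 0.635% against 0.895%). PU.1, the myeloid factor, HNF4A of the liver, GRHL of epithelia, SOX, T-box, LIM homeobox, ETS and YY1 did not pass the test, and HNF1 had 0 matches.

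In Fisher's exact test adjusted over 26 motifs, 16 were enriched and 1 depleted, with an adjusted p from 1.12e-202 (NEUROD) to 0.0261 (ROR) for the enriched motifs other than CTCF and AP-1, whose p was too small to be represented. Control windows matched also on CpG number, a choice made after seeing the data, ended the call for CRE (log2 ratio 0.24), and keeping the upper 50% of the peaks by signal ended those for NFI, ROR, REST and TEAD; ROR was also lost with the 100 bp window and with flanking control windows, so that it stayed in 3 of 6 alternatives. With control windows 1 kb to either side, not matched on GC, the direction turned for POU (−0.10), RUNX (−0.25) and LIM homeobox (−1.40).

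Within peaks, footprints were matched most often, relative to moved intervals, by the CTCF and NRF1 motifs. Over 426102 footprints, CTCF matches overlapped 1.10%, against 0.0192% of intervals moved within the same peaks (log2 ratio 5.83). NRF1 had a log2 ratio of 4.90, CRE 3.57, EGR 3.51, NFI 3.28, SP/KLF 2.88, RFX 2.58, NEUROD 1.58, REST 1.42, YY1 1.24, ETS 0.98, AP-1 0.77, MEF2 0.44 and MYOD 0.41. Matches fell less often in footprints than in moved intervals for ROR (−0.81), GATA (−0.62), LIM homeobox (−0.60), POU (−0.52), RUNX (−0.39) and SOX (−0.38). In the exact test 14 motifs were enriched and 6 depleted, and 12 were enriched in both peaks and footprints. Of the motifs called in footprints, MEF2, ETS, REST, MYOD, ROR and RUNX passed in 3 of 4 alternatives, and the others in all 4. The GC content was 63.1% in footprints and 54.9% in moved intervals, so GC was not matched here. In distal peaks alone, the T-box motif, at −0.03 over all footprints, had 0.27.

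**Figure D3:**
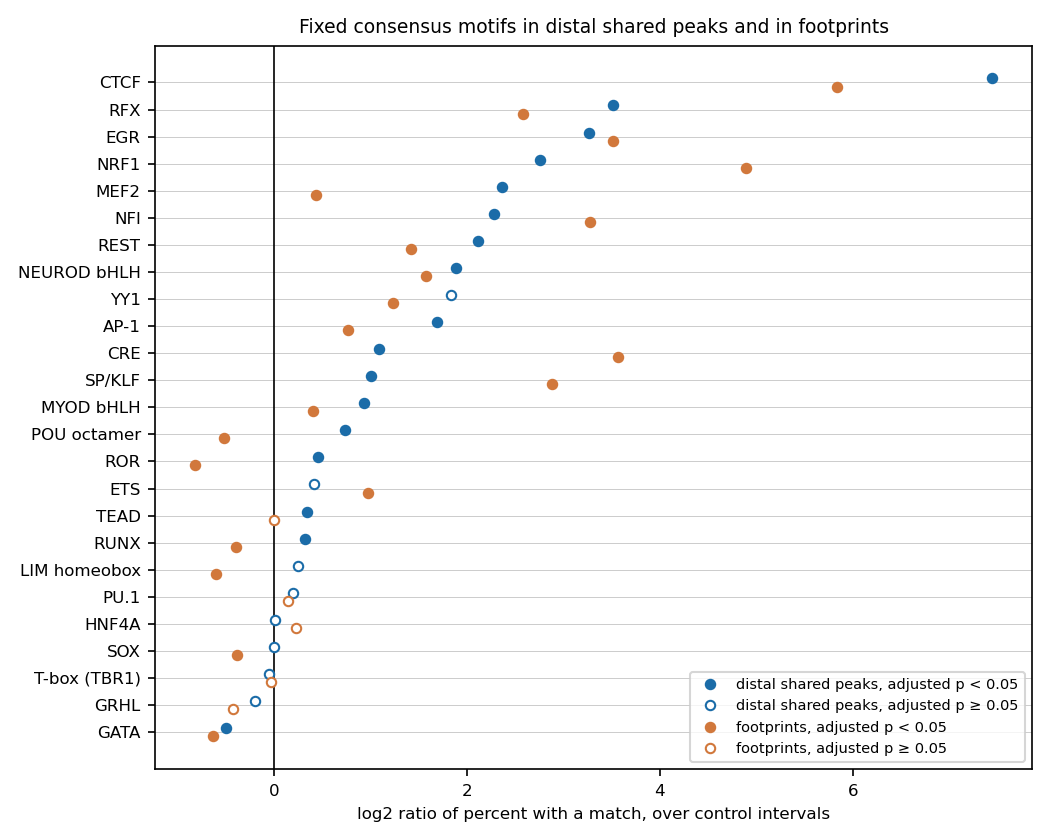
Log2 ratio of the percent of intervals with a motif match over control intervals, for distal shared peaks (blue) and for footprints (orange); filled points passed an adjusted p of 0.05 in Fisher's exact test. HNF1, which had 0 matches in peaks and footprints, is not drawn. CTCF has the highest ratio in both (7.44 and 5.83).

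The X chromosome held fewer peaks per Mb than any autosome in both females. It had 18.1 peaks per Mb in replicate 1 and 18.6 in replicate 2, whereas the autosomes ranged from 40.2 to 72.9 and from 38.7 to 68.0. The ratio to the autosome median was 0.361 ± 0.020 (SD, n = 2), beside a ratio of 0.722 for protein-coding genes per Mb. It was 0.523 for promoter peaks and 0.311 ± 0.027 (SD, n = 2) for distal peaks. A promoter peak was present at 46.6% ± 0.75 of the X genes and 61.8% ± 0.45 of the autosomal genes (SD, n = 2). In the tertile of promoters with most CpGs, 96.4% of 138 X promoters had a peak in each library, close to the 97.6% and 97.2% of 7218 autosomal promoters, but the median signal was 1.54 and 1.62 on X against 3.41 and 3.80 on autosomes. Over all peaks the difference was smaller, with a ratio of X to autosomal median signal of 0.763 and 0.730. Xist, the RNA gene that silences the inactive X (chromosome X, 103460366 to 103483254), had a promoter peak in both libraries with a signal of 0.990 ± 0.291 (SD, n = 2). These are values per library with no test across animals.

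**Figure D4:**
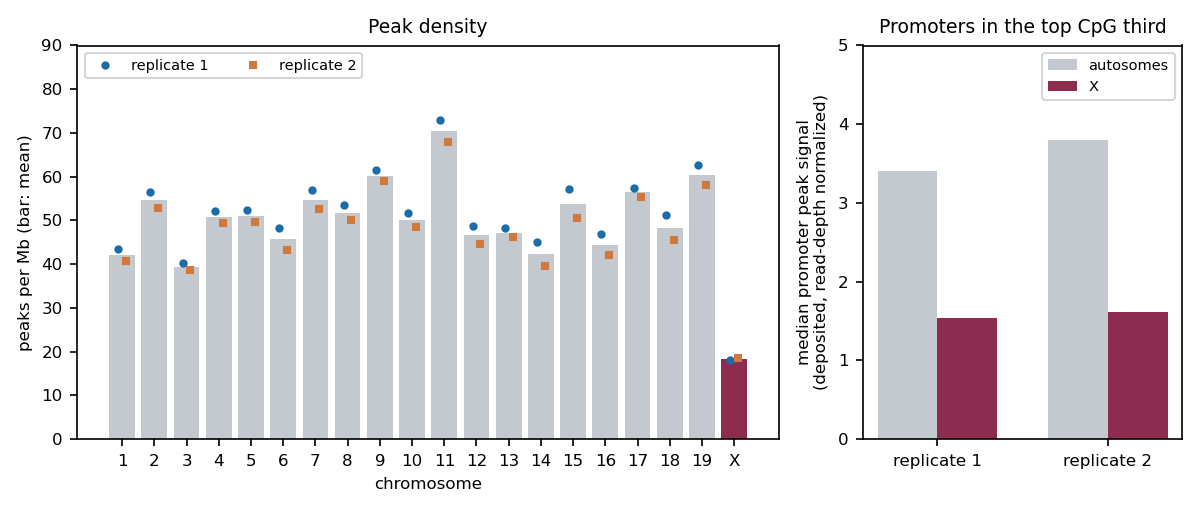
Left, peaks per Mb on each chromosome, with bars for the mean of the 2 libraries and points for each library. Right, median signal of promoter peaks in the tertile of promoters with most CpGs, on autosomes and on X, in each library. X lies at 18.1 and 18.6 peaks per Mb, and its promoters at 1.54 and 1.62 against 3.41 and 3.80.

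Between the animals, loci of some neuronal lists had higher signal in replicate 1, and those of other neuronal lists did not stand out. After centring, the median log2 ratio of replicate 1 over replicate 2 at shared distal peaks was 0.19 for telencephalic transcription factors, 0.18 for cerebellar neurons, 0.17 for excitatory neurons, 0.14 for upper cortical layers and 0.14 for the glutamatergic synapse. These 5 lists lay above the central 95% of random lists, at percentiles from 98.4 to 99.8. Inside it were deep cortical layers at 0.06 (percentile 82.5), inhibitory neurons at 0.03 (70.1), hippocampal neurons at 0.02 (66.9), ion channels at 0.02 (51.0), immediate early genes at −0.01 (53.1) and striatal neurons at −0.02 (36.9). The lymphocyte list lay below it, at −0.24 (percentile 0.32), and of the 26 lists 1.3 would lie outside by chance. Oligodendrocyte loci had −0.16 (percentile 3.51), astrocyte loci −0.05 (26.3), endothelial and pericyte loci −0.06 (23.5), oligodendrocyte precursor loci −0.03 (36.2) and microglial loci −0.01 (60.8). With 1 library per animal these values have no test. With promoters included, the lymphocyte list was no longer below its range (percentile 21.9), the glutamatergic list was no longer above it (median log2 ratio 0.11), and the deep-layer list lay above it (percentile 99.9). With footprint counts in place of signal, the telencephalic and cerebellar lists stayed above and the excitatory (96.6), upper-layer (91.8) and glutamatergic (87.7) lists did not, inhibitory neurons (99.4), epithelia (98.95) and immediate early genes (97.7) lay above, and astrocytes lay below (0.15); with ranks of signal the cerebellar list (97.2) and the lymphocyte list (4.58) lay inside.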

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

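The test of male-specific genes was chosen only after the Y peaks had been seen; the test of shared sequence was not, but its split by the cluster was. Both females had peaks on the Y chromosome: 54 in each library, 71 after merging and 35 found in both. The numbers of peaks and the shares found in both animals include them, whereas the tests of lists and motifs do not. The Y peaks stood out because a female genome has no Y, and there were no control samples to set them against. Of the 35, 20 lay in a cluster from 90717581 to 90744820, and the strongest had a mean signal of 4.31.

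The tables argue against male DNA or a mislabelled animal. Of 7 male-specific genes (Sry, the testis-determining gene, Ddx3y, Uty, Kdm5d, Eif2s3y, Zfy1 and Usp9y), 0 had a peak within 1 kb of their start site in either library, whereas 6 of 6 homologues on X (Ddx3x, Kdm6a, Kdm5c, Eif2s3x, Zfx and Usp9x) had one in both. Reads from sequence that Y shares with other chromosomes stay open: in the median shared Y peak, 46.2% of the 31-base words also occurred on X or an autosome, against 4.62% in random Y windows, but this lay between the bounds set in advance for and against that source. The median joins unlike peaks: all 15 shared peaks outside the cluster had 53.3% to 100% of their words elsewhere, whereas 19 of the 20 in the cluster had under 50%, and 4 of them had 0%. Sequence of the CAST/EiJ parent that the reference lacks was not tested, nor was any biological explanation of the cluster.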

How the results depend on the processing

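Tests with the smaller peak list and with control windows matched on GC and CpG number were chosen only after the results were seen; the other alternatives were set before the data were examined. No paired analysis was possible because there is 1 group. Over 121 results and 735 alternatives, 657 kept their direction and their side of the threshold or moved by less than the spread, 32 lost the threshold, 20 gained it, 4 turned direction and 22 values moved. A change of sign between values that both missed the threshold was not counted as a turn. By kind, results stayed the same in 140 of 156 alternatives for promoter lists, 218 of 234 for distal lists, 140 of 156 for motifs in peaks and 96 of 104 for motifs in footprints. Most lists had not passed the main test, so many of these had no call to lose. Losses numbered 13 for the 7 called distal lists, 6 for promoter lists, 7 for motifs in peaks and 6 for motifs in footprints. A mean per library with 1 library left out always lies within the SD, so it counted as kept by construction.

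Directions turned for POU (−0.10), LIM homeobox (−1.40) and RUNX (−0.25) with control windows 1 kb to either side, and for the T-box motif in footprints of distal peaks (0.27); the flanking windows had a GC content of 44.8% against 52.7% in the peaks, and the cause was not tested further. The upper 50% of the peaks by signal gave 61707 peaks and 16.5 Mb per library, 38.9% of shared peaks at promoters, an X ratio of 0.255 and 2 depleted motifs; 10 lists lay below in promoters in place of 7, with endothelial cells and pericytes (−45.2 percentage points from other genes), meningeal fibroblasts (−30.2) and choroid plexus and ependyma (−30.2) gained, and the glutamatergic synapse (24.9) was gained above. The smaller list gave 72542 peaks, 16.1 Mb, 39.1% and an X ratio of 0.328, and gained endothelial cells and pericytes (−35.5). Promoters within 1 kb gained choroid plexus and ependyma (−30.4) and brought muscle from −59.5 to −26.7. Fewer peaks and less length follow from the construction; the cause of the other moves was not tested. The mean share of peaks found in both animals was 52.5% with reciprocal overlap of 50%, 85.6% with equal numbers of the strongest peaks, and 74.5% against listed cut-rate positions. Over all merged peaks with the lowest FDR, Spearman's rho was 0.504. The promoter share was 37.4% with a window of 2.5 kb, 30.8% with reciprocal overlap of 50%, 25.8% with hotspots, and 23.8% to 25.8% with 1 library left out, where peaks of 1 animal enter. With matching on promoter CpG, the 3 lists above all lost their call and the glutamatergic synapse list gained one, so that 1 list lay above in place of 3. Loci of 50 kb left 3 lists with more distal peaks in place of 7. Without replicate 1, the promoter call was gained for choroid plexus and ependyma (−29.7 percentage points from other genes), the distal call was lost for ion channels (26.8 percentile points above random lists) and imprinted genes (15.3), and ETS (0.88) and LIM homeobox (0.24) were gained in peaks. Without replicate 2, the promoter call was gained for endothelial cells and pericytes (−26.5), the distal call was lost for imprinted genes (17) and gained for inhibitory (26) and striatal neurons (34.3), YY1 (1.69) was gained in peaks, and ROR (−0.35) and REST (0.97) were lost in footprints. Depleted motifs numbered 3 with flanking windows and 2 with controls matched on GC and CpG. Weak sites set the limits: in the lowest decile of signal 12.9% and 20.5% of peaks were found in the other animal, so a peak in 1 animal alone does not show a difference. With 2 animals, differences between animals have no test.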

Other observations

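The tests of X gene density, of the 4 escape genes Ddx3x, Kdm6a, Kdm5c and Eif2s3x, and of the glial and vascular lists were chosen only after the results were seen, as were the descriptions of motifs and lists in peaks of 1 animal. Motif matches in peaks found in 1 animal were counted, with no test. The CTCF motif matched 7.22% of distal shared peaks, 0.287% of those in replicate 1 only and 1.65% of those in replicate 2 only. AP-1 matched 7.15%, 3.95% and 6.52%, NEUROD 3.59%, 1.68% and 2.55%, and RFX 0.413%, 0.135% and 0.276%. SOX matched 1.55%, 1.49% and 1.67%, and TEAD 1.05%, 1.05% and 1.09%. Shared peaks had a median width of 260 bp, against 131 bp and 126 bp for those of 1 animal, and 3.62 CpGs per 100 bp against 1.91 and 2.05. A shared peak joins overlapping peaks of both libraries, so part of its greater width follows from the merging.

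Summed over the loci of all protein-coding genes, replicate 1 had 1.30 times as many peaks of its own as replicate 2 (38216 against 29304), and 6951 genes had more in replicate 1 and 5967 more in replicate 2. Of the 26 lists, the 7 highest ratios were 2.89 in loci of telencephalic transcription factors (191 against 66), 2.97 for inhibitory neurons (98 against 33), 3.05 for immediate early genes (61 against 20), 3.22 for hippocampal neurons, 3.73 for epithelia, 3.62 for muscle and 5 for the Hox list (30 against 6). The ratio was near that of all loci for excitatory neurons (1.34), upper layers (1.34) and the glutamatergic synapse (1.33), which are 3 of the 5 lists with higher signal in replicate 1. More genes had the excess in replicate 1 than in replicate 2 among telencephalic factors (14 against 2), immediate early genes (14 against 2), inhibitory neurons (13 against 4), epithelia (12 against 3), hippocampal neurons (9 against 2), muscle (9 against 5) and the Hox list (5 against 3). Astrocyte loci went the other way, with 32 in replicate 1 only and 62 in replicate 2 only, and 14 genes had more in replicate 2 against 5; the ratio was also under 1 for ribosomal proteins (0.818; 7 genes against 5) and endothelial cells and pericytes (0.909; 9 against 5). For microglia (0.719) and erythroid cells (0.769) it was under 1 as well, but there more genes had the excess in replicate 1 (5 against 2 and 5 against 4). Loci of neighbouring genes overlap, as for neighbouring Hox genes, so 1 peak can count at more than 1 gene of a list. The genes in these counts are therefore not independent. Of the 5 strongest peaks of replicate 1 that touch no hotspot of replicate 2, 3 lay at Nr2f1, a nuclear receptor gene of cortical area patterning (chromosome 13, 78197861 to 78199720; highest signal 1.41), and another in an exon of Mn1 (1.30). Those of replicate 2 lay in an intron of Alox12 (1.76), in intergenic sequence nearest to Olfm1 (1.56), at the TSS of Pcdhga11 in the protocadherin gamma cluster (1.47), in an intron of Zfhx2 (1.46) and in an exon of Cep170b (1.43). Single members stood apart from their lists: Tle4, a corepressor gene of deep-layer neurons, had a promoter signal of 7.57 ± 1.22 (SD, n = 2) but 1 distal peak, and Ube3a had 5.52 ± 0.75 (SD, n = 2) with 0. Of the words of the 5 strongest shared peaks, 0% occurred in the mitochondrial genome, and 1.7% of 1000 random shared peaks had over 50% of their words at more than 1 nuclear place.

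The low peak density on X is a pattern for which closing of 1 X copy in each female cell is a candidate explanation. Lower gene density is argued against, since the residual of X from the autosomal line of peak density on gene density was −5.43 residual SDs in the nearer library, and so is repeat content, since outside soft-masked repeats the ratio to the autosome median still was at most 0.445. Closing of 1 copy met its test at promoters rich in CpG, where X signal was at most 0.450 of the autosomal signal; over all peaks the ratio of the medians was 0.763 and 0.730, and why it was higher there was not tested. The escape genes Ddx3x, Kdm6a, Kdm5c and Eif2s3x lay near or above the autosomal median (4 of 4), but they were picked after their high signal had been seen and so lend the explanation no support. In a further set named in advance, 2 of 5 genes lay above the X median, which is the bound set against closing of 1 copy. Pbdc1 and Utp14a lay above it, at 1.03 to 1.10 of the autosomal median over both libraries. Car5b (0.737 ± 0.207), Shroom4 (0.685 ± 0.038) and Mid1 (0.128 ± 0.182, SD, n = 2 each) lay below. Promoters were not matched on CpG number here, with 25 CpGs at Car5b and 12 at Mid1, but 52 at Shroom4. By the bound set in advance, the outcome went against closing of 1 copy. CpG number, which the bound did not consider, limits the test at Car5b and Mid1, where the make-up of the promoters cannot be separated from a closed copy. It does not set Shroom4 apart, since Pbdc1 had 48 CpGs and Utp14a 50. The test at CpG-rich promoters and the test of further genes point in different directions, so the hypothesis stays open. Neither males nor alleles were analysed here.

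The higher signal of 5 lists in replicate 1 may be technical or may come from the tissue taken; no biological explanation was tested, since the design names none between the animals. GC content is argued against for these 5 lists, since 5 of 5 stayed above their random range once each peak was set against peaks of the same GC. It did bear on other lists. Deep cortical layers went from a log2 ratio of 0.06 (percentile 82.5) to 0.18 (99.75), above the central 95% of random lists. The lymphocyte list went from percentile 0.32 to 4.7, inside it. Against peaks of the same signal 3 of 5 stayed, while upper layers went from a log2 ratio of 0.14 to 0.12 (percentile 97.4) and the cerebellar list from 0.18 to 0.11, with an upper bound of its random range of 0.16 before and 0.17 after. Without shared peaks near a peak of replicate 1 alone 2 of 5 stayed (excitatory and telencephalic), and the lost lists kept most of their ratio, at 0.17 for the cerebellar list, 0.13 for upper layers and 0.12 for the glutamatergic synapse, while their upper bounds rose from 0.16 to 0.21, from 0.13 to 0.15 and from 0.12 to 0.13, so neither signal strength nor wider stretches is settled as a source. Fewer glial and vascular cells in replicate 1 also stay open, with 0 of 5 such lists below their range by signal and none above, and astrocytes alone of these 5 below by footprint counts (percentile 0.15).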
